A study of Homo sapiens with 6 samples.

How the data were processed

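Gene expression was measured in Jurkat cells, a human leukaemia T cell line, on 6 one-colour Agilent arrays carrying probes for coding genes and long non-coding RNAs. Per the labels, 3 arrays held cells cultured with phorbol 12-myristate 13-acetate (PMA), which activates protein kinase C, and ionomycin, which lets calcium into the cell, and 3 held cells cultured without them. The labels' treatment protocol gives 10 ng/mL PMA and 500 ng/mL ionomycin for 24 h, and its text is the same for all 6 samples. The sample titles carry a number and a code that differs between the labelled groups and does not name PMA or ionomycin, so the groups rest on the treatment label alone. Nothing in the labels says that the samples of a group came from separate cultures, so the p-values measure only the spread between these samples, which may be technical.

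The scanner files hold the intensity of each spot on a linear scale, per the file headers from Agilent Feature Extraction 10.5.1.1 with array design 039494, a single Cy3 channel and probe positions on the human genome build hg19. Per the file headers, the processed intensity is background-subtracted and detrended within an array, with substitute values for spots near background, and is not normalised between arrays. All 6 arrays lay on 1 slide and were scanned in 1 run. The deposited value table holds log2 values of 29521 probes. From a comparison with the scanner files, its values are centred per probe on the median of the 3 arrays labelled without PMA and ionomycin, and its direction is that of the scanner values. Its normalisation between arrays is not given in the sources used here. The medians of its columns lie between -0.004 and 0 on the log2 scale.

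Each array had 58717 spots for 50599 probes besides the control spots. Between 213 and 451 spots per array carried an outlier flag and were left out, and 0 spots were saturated. The log2 processed intensities of a probe's spots were averaged, and each array's 75th percentile was subtracted. A probe counted as well above background on an array where at least 50 percent of its spots did. Probes well above background on every array of at least 1 group were tested, which kept 40029 probes. A gene was represented by its probe with the highest mean signal, giving 29378 genes, of which 6858 had more than 1 tested probe. Names were updated through a RefSeq gene table of the GRCh38 assembly, used for names only, where 34436 probes matched and 16163 kept the name of the array's design. Non-coding probes were defined by accession or name pattern, 14075 on the array, and the pattern misses non-coding genes listed under other accessions.

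Differences are the arrays labelled with PMA and ionomycin minus those labelled without, on the log2 scale. They were tested with the moderated test of limma 3.58.1 in R 4.3.3 (lmFit and eBayes) and adjusted with the Benjamini-Hochberg method over the 40029 probes, with a threshold of 0.05. The 21 gene lists were tested with camera at a preset correlation of 0.01 between genes, which compares a list with all other genes, and again with an estimated correlation. The second form has 4 degrees of freedom here, so it can lose a call for that reason alone. They were also tested with fry, which asks whether a list's genes move on balance one way. List p-values were adjusted over the 21 lists. The interval of a median over genes came from 10000 resamples of the genes. For a probe not well above background on any array of a group, the fold is given as a bound, the mean of the bright group against the mean, per array, of the higher of the probe's own signal and the lowest signal among probes well above background. No fold is given where that bound is under 1.

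The lists, the tests, the alternatives and the rule for named genes were fixed before the data were examined. The rule took the 10 genes with approved-style symbols and the 5 non-coding genes with the largest moderated t in each direction, as fewer than 5 genes passed, up to 4 members of each list by absolute t, and IL2, CD69, EGR1, FOS, IFNG, TNF, IL2RA, NFATC1, SMPD1, LOC100506036 and LOC100652951. LOC100652951 was not found under that name and is not analysed here. A few list members that the rule takes are not reported here. The alternatives were a normexp background correction with an offset of 50, quantile normalisation, median scaling, no detection filter, detection on all 6 arrays, the deposited value table, a variance trend with robust estimation, the title number as a block, the place on the slide as a block, each array left out, a fold of at least 2 besides, and the mean over a gene's probes. A restriction to probes with a mean signal of at least -2, relative to the 75th percentile, was added after seeing the data, as was a list test that gives camera each list's estimated correlation (at least 0) as a fixed value and keeps the degrees of freedom of the preset form. The normexp offset shrinks log2 differences of dim probes by construction.

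The fits were tested on simulated arrays with the means and spreads of the real probes, in 20 runs. With 200 of 40021 probes changed, 48.6 percent of 2-fold and 79.8 percent of 4-fold changes passed the adjusted threshold. With 2000 changed, the shares were 72.4 percent and 92.3 percent. A 25-gene list raised by 0.5 was called by camera in 100 percent of runs and an unchanged list in 0 percent. The simulated arrays took means and spreads from the real probes, and no correlation between genes is stated for them. The real lists had estimated correlations of up to 0.56, against the preset 0.01. The other splits of the real arrays into 3 and 3 called from 1 to 14 lists. The 0 percent therefore cannot be taken as the rate of false calls for the real lists. The number of arrays limits the precision, and an exact permutation test of 3 arrays against 3 cannot give a two-sided p under 0.1.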

Results

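The 6 arrays came from Jurkat cells, 3 labelled as cultured with PMA and ionomycin (title numbers 2, 3 and 4) and 3 labelled as cultured without (title numbers 1, 2 and 3). PMA and ionomycin together bypass the T cell receptor and are a standard way to activate T cells. The series design asks which long non-coding RNAs differ in expression between these cultures. The share of probes well above background was 83.4%, 80.4% and 83.0% on the arrays labelled with PMA and ionomycin and 79.9%, 66.7% and 74.3% on those labelled without. Pearson correlations of log2 signal across probes lay between 0.9945 and 0.9969 within the treated label, 0.9895 and 0.9904 within the control label, and 0.9877 and 0.9940 between labels. Control replicate 3 correlated at 0.9923 to 0.9940 with the arrays of the treated label, above its 0.9895 and 0.9904 with the other control arrays.

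The genes that mark T cell activation had similar levels under both labels. CD69, an early activation marker on the T cell surface, had a log2 signal relative to the 75th percentile of 0.90 ± 0.30 (SD, n = 3) on the arrays labelled with PMA and ionomycin and 0.95 ± 0.20 (SD, n = 3) on those labelled without. Its log2 difference was -0.05, with a 95% interval from -0.50 to 0.40. The log2 difference of EGR1, an immediate early transcription factor, was 0.05, with an interval from -1.13 to 1.23. FOS, a subunit of the AP-1 transcription factor, differed by 0.25 (interval -0.27 to 0.76) and TNF, an inflammatory cytokine, by 0.23 (interval -0.46 to 0.91). IL2RA, the alpha chain of the interleukin-2 receptor, differed by -0.15 (interval -0.73 to 0.44), and NFATC1, a transcription factor activated by calcium signalling, by -0.06 (interval -0.35 to 0.24). None of these 6 genes passed, with limma adjusted p-values from 0.740 for FOS to 0.987 for EGR1. Because these genes did not separate the labels, groups are named below by their label.

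IL2 is the cytokine that Jurkat cells are known to secrete on activation. It was well above background on 3 of 3 arrays labelled with PMA and ionomycin and on none of the 3 labelled without. The lowest log2 intensity counted as well above background, before scaling, was 3.78, 4.39 and 3.75 on treated replicates 2, 3 and 4. On control replicates 1, 2 and 3 it was 3.94, 4.96 and 4.64. The difference in detection may therefore partly reflect the sensitivity of the arrays, which was not tested. The mean log2 signals of IL2, -6.31 ± 0.21 and -7.57 ± 0.40 (SD, n = 3 each), were both near the lower end of the scale. The bound on its fold was under 1, so no fold is given. The log2 difference of 1.25 (SE 0.22) had a limma adjusted p of 0.225. The call depended on 1 array: without control replicate 3 the difference was 1.48 and the adjusted p 0.0196. IFNG, which encodes interferon gamma, was not well above background on any array.

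**Figure D1:**
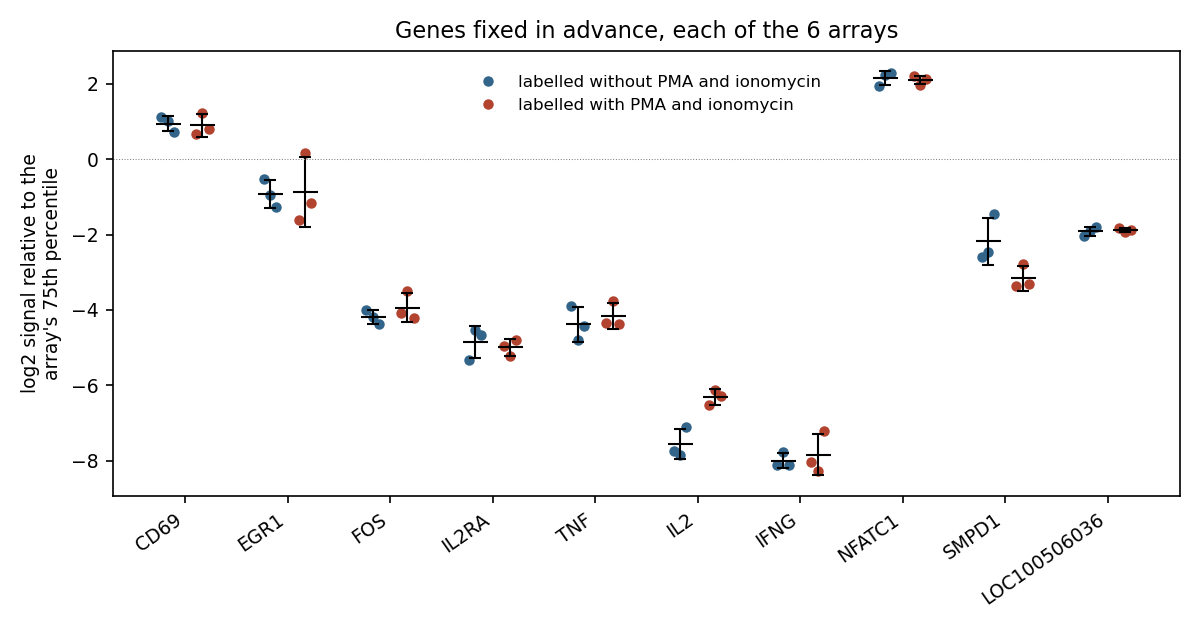
Log2 signal relative to each array's 75th percentile (vertical axis) for 10 genes fixed in advance (horizontal axis), with 1 point per array, 3 arrays labelled without PMA and ionomycin in blue and 3 labelled with them in red; horizontal bars are means and whiskers are SDs. The labels overlap for CD69, EGR1, FOS, IL2RA, TNF, IFNG, NFATC1 and LOC100506036, while for IL2 and SMPD1 the 3 arrays of each label do not overlap.

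Over the 69 measured genes of the immediate early, activation marker and cytokine lists, the median log2 difference was -0.01 (95% interval over genes -0.04 to 0.05) and the mean was 0.05, so their signs differ. The fitted differences ranged from -0.28 to 1.25, the highest that of IL2, for which no fold is given. At 1 probe per gene, IL2 was the only 1 of the 69 genes with a fitted difference of 2-fold or more, while another probe of NR4A2 differed by 1.32. With IL2 at its bound the median was -0.01 and the count 0. That bound is a lower limit, so it cannot show that IL2 differed by less than 2-fold. Of the 62 that were well above background on all 6 arrays, 0 differed by 2-fold. For 58 of the 69, the 95% interval of the difference ended below a 2-fold rise. The exceptions were CCL3, CCL4, CCL5, EGR1, EGR2, EGR3, IL2, IL32, NR4A3, TNFRSF9 and XCL1.

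No probe passed the threshold in the comparison of the labels. The limma test gave 0 of 40029 probes, 0 of 29378 genes and 0 of 9639 non-coding probes at an adjusted p under 0.05, with a smallest adjusted p of 0.161. At an unadjusted p under 0.05 there were 5015 probes, 4613 higher and 402 lower on the arrays labelled with PMA and ionomycin. Among the 17320 tested probes with a mean signal of at least -2, the split in the same fit was 585 higher and 283 lower. Other fits gave 2914 higher and 1157 lower under quantile normalisation, and 3480 and 868 under median scaling. Fitting only those 17320 probes gave 901 and 651. A normexp background gave 2634 and 499, detection on all 6 arrays 3154 and 487, and no detection filter 5097 and 712. The 3 arrays of each label did not overlap for 5621 genes, or 19.1%. Of these, 4431 were higher and 1190 lower under the PMA and ionomycin label. Chance gives 10% on average over splits of the arrays. Genes are correlated, so a single split can lie far from that average, and no share is given for the other splits. The count of probes past the adjusted threshold depended on 1 array. Without control replicate 3, 1568 probes passed, 1564 of them higher, and 86.9% of the 1568 had a mean log2 signal below -2. Median scaling gave 4 probes, all higher. It also moved the median difference of all probes from 0.06 to -0.06 on the log2 scale.

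The genes with the largest moderated t toward higher signal, none past the threshold, were mostly dim. SLC7A10, an amino acid transporter well above background on 1 of 3 arrays labelled without PMA and ionomycin, differed by 1.28 (SE 0.11) and FOXQ1, a forkhead transcription factor, by 1.43 (SE 0.15). RYR3, a calcium release channel, differed by 0.92 (SE 0.10). The other 7 were not well above background on any array labelled without PMA and ionomycin, so their folds are bounds. GUCY2F, a guanylate cyclase of photoreceptors, was at least 2.01-fold higher, the antisense RNA CADM3-AS1 at least 1.85-fold, and SNX31 at least 1.57-fold. The bounds were 1.47-fold for the pseudogene TMEM14EP, 1.27-fold for the antisense RNA CLIP1-AS1, 1.15-fold for LRRTM2 and 1.04-fold for APCDD1L. All 10 had a limma adjusted p of 0.220, and each was higher on every array labelled with PMA and ionomycin than on any labelled without. With a normexp background, whose offset shrinks differences of dim probes, the log2 differences of these 10 were smaller, from 0.25 for APCDD1L to 0.85 for FOXQ1, and those of GUCY2F (0.42), CADM3-AS1 (0.25) and SNX31 (0.36), among others, lay under their bounds.

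The genes with the largest moderated t toward lower signal had smaller fitted differences than those above, and none passed. Most of those above have only bounds, down to 1.04-fold for APCDD1L, so the sets are not ranked by size. WNT2B, a Wnt ligand, differed by -0.67 (SE 0.12), the zinc finger gene ZNF713 by -0.46 (SE 0.09) and TBXA2R, the thromboxane A2 receptor, by -0.58 (SE 0.12). SRD5A2, a steroid 5-alpha reductase, differed by -0.79 (SE 0.16), QPCTL, a glutaminyl cyclase, by -0.60 (SE 0.14) and HYAL4 by -0.58 (SE 0.14). FAM118A differed by -0.52 (SE 0.13), APEH, an acylpeptide hydrolase, by -0.38 (SE 0.09), MIR23AHG, a microRNA host gene, by -0.30 (SE 0.07) and ESYT3 by -0.62 (SE 0.15). Their limma adjusted p-values ran from 0.226 for WNT2B to 0.261 for ESYT3. Other probes of HYAL4, ESYT3, TBXA2R and ZNF713 differed with the opposite sign, up to 1.73 for HYAL4. The other tested probe of FAM118A differed by -0.02. With a normexp background WNT2B differed by -0.27 and SRD5A2 by -0.32.

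Among non-coding RNAs, the largest moderated t toward higher signal were those of CLIP1-AS1 and 4 transcripts named by locus. XLOC_013057 was at least 1.27-fold and XLOC_014070 at least 1.63-fold higher. The log2 differences were 0.89 (SE 0.09) for XLOC_007038 and 1.14 (SE 0.13) for XLOC_006781, each with a limma adjusted p of 0.220. Toward lower signal, XLOC_008342 on chromosome 10 (hg19 2612547 to 2612606) differed by -2.31 (SE 0.40, limma adjusted p = 0.225), while another probe of it differed by 0.32. XLOC_008575 differed by -1.17 (SE 0.22), XLOC_005209 by -1.58 (SE 0.36), XLOC_011136 by -1.14 (SE 0.27) and MIR23AHG by -0.30, none past the threshold. With a normexp background the differences were 0.31 for XLOC_013057 and 0.28 for XLOC_014070, both under their bounds, 0.25 for XLOC_007038, 0.16 for XLOC_006781, -1.30 for XLOC_008342, -0.52 for XLOC_008575, -0.54 for XLOC_005209 and -0.60 for XLOC_011136. LOC100506036, a long non-coding RNA now named CNNM3-DT, has its probe on chromosome 2 (hg19 97477992 to 97478051). Its log2 signal was -1.88 ± 0.06 under the PMA and ionomycin label and -1.92 ± 0.12 under the other (SD, n = 3 each), a difference of 0.04 with a 95% interval from -0.19 to 0.27. SMPD1, which encodes acid sphingomyelinase, differed by -0.98 (SE 0.34), with a limma adjusted p of 0.331 and 3 of 3 arrays below all 3 of the other label. Without control replicate 3 it differed by -0.63, and with the place on the slide as a block by -0.57.

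At an unadjusted p under 0.05, non-coding probes were over-represented, with 18.1% of 9639 against 10.8% of 30390 other probes (Fisher's exact test across probes, two-sided, odds ratio 1.84, p = 2.18e-75; probes are not independent replicates). Non-coding probes were also dimmer, with a median log2 signal of -4.03 against -1.93. Among probes with a mean signal of at least -2, a level chosen after seeing the data, the shares in the same fit were 9.33% of 1940 and 4.47% of 15380. A separate fit of those probes alone gave 13.6% and 8.38%. Non-coding probes were dimmer there too, with a median of -0.53 against 0.94, so the restriction does not remove the difference in brightness.

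The difference between the labels followed probe brightness. Probes with a mean log2 signal below -6 had a median difference of 0.62, those from -6 to -5 of 0.29, those from -3 to -2 of 0.06, and those of 2 and above of -0.01. The 7400 probes below -5 had a median difference of 0.36, which was 0.03 with a normexp background and 0.05 under quantile normalisation. It was 0.11 for the 1109 of these probes that were well above background on all 6 arrays, while the filter also kept probes that were so under 1 label only. Of the 17320 probes with a signal of at least -2, 78 differed by 2-fold or more, 72 higher and 6 lower.

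**Figure D2:**
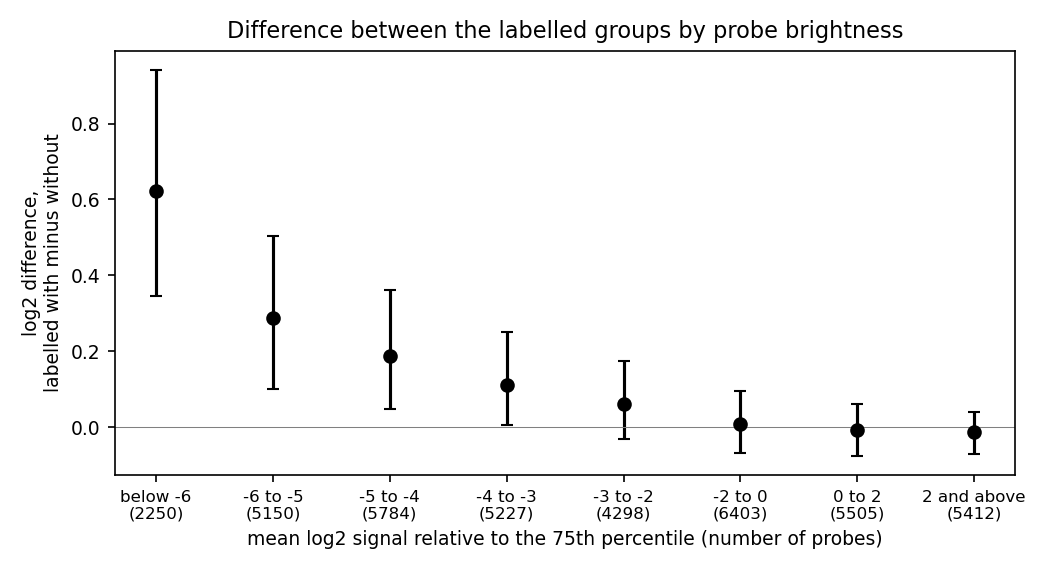
Median log2 difference between the labels (points) with its quartiles over probes (whiskers) on the vertical axis, by mean log2 signal relative to the 75th percentile on the horizontal axis, with the number of probes in each bin. The median falls from 0.62 in the dimmest bin to -0.01 in the brightest under the main processing.

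Of the 562 measured genes of the 21 lists, 0 passed over all genes tested, 24 had an unadjusted p under 0.05 and ORAI3 differed by more than 2-fold, while IL2 had a fitted difference of that size with no fold given. Adjusted over the list alone, 2 genes passed, CCL5 and IL2, both in the cytokine list. Without control replicate 3, 4 list genes passed over all genes tested, CA9, CCL5, IL2 and KRT18. Camera with the preset correlation placed 12 lists below the other genes and none above. With an estimated correlation it placed none, with a smallest adjusted p of 0.324 on 4 degrees of freedom, and fry called none, with a smallest adjusted p of 0.905. The median difference of all probes was 0.06, so a list with a median near 0 lay below the other genes. Under quantile normalisation, which moved that median to -0.01, 0 lists were called. The medians of the cytokine list and of the markers of other cell types were both -0.05 there. Median scaling lowered every difference by the same amount, so that all 21 list medians were below 0, and left each list where it was relative to all probes.

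**Figure D3:**
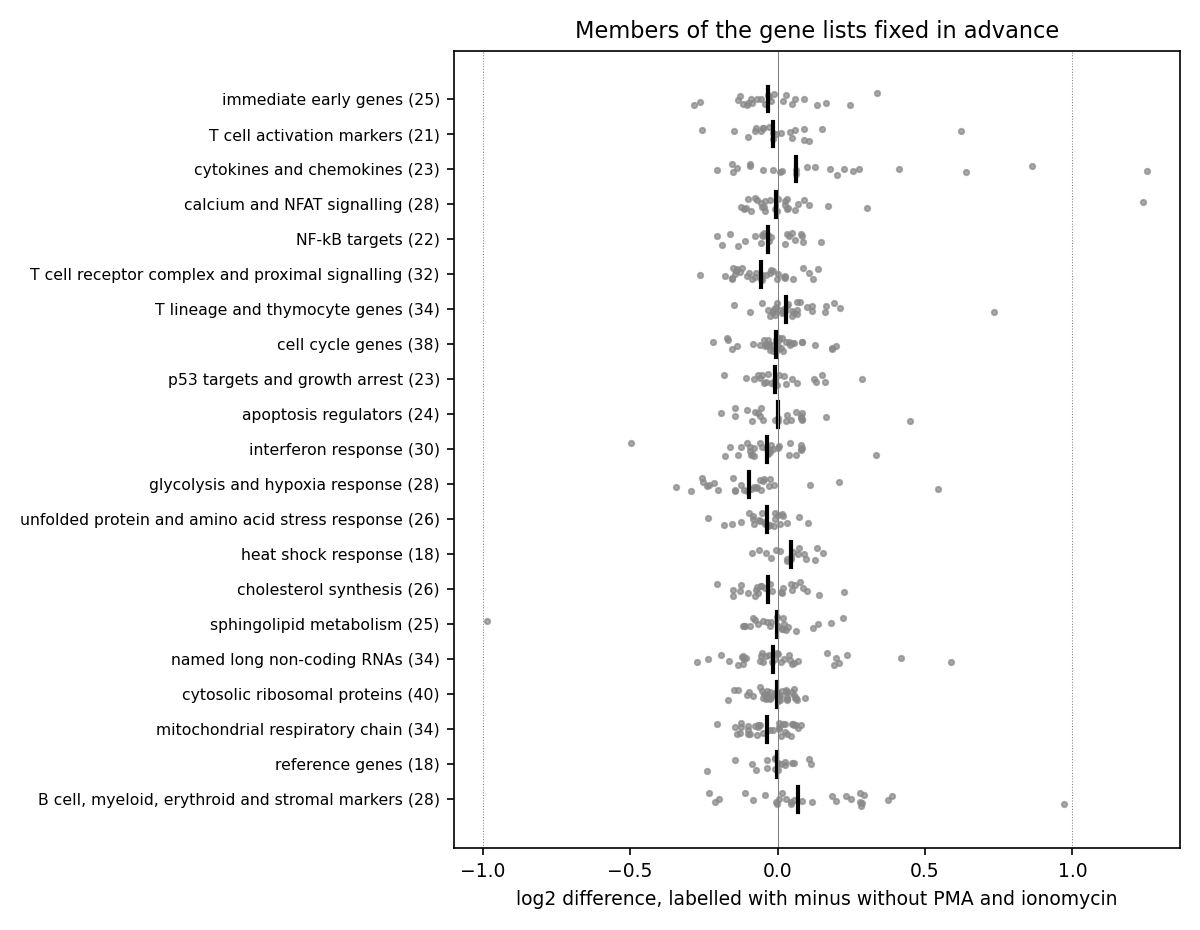
Log2 difference between the labels (horizontal axis) for each measured member (grey points) of 21 gene lists fixed in advance (vertical axis, number of members in brackets), with the list median as a black bar and dotted lines at a 2-fold difference. All list medians lie between -0.10 and 0.07, and the fitted differences of 2 members, IL2 and ORAI3, lie beyond the dotted lines; for IL2, not well above background on the arrays labelled without PMA and ionomycin, no fold is given.

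Of 25 immediate early genes, 0 passed, 9 had positive and 16 negative differences, and the median was -0.03. DUSP2, a phosphatase of MAP kinases, differed by -0.26, NR4A2, a nuclear receptor, by 0.34, and JUND, a subunit of AP-1, by -0.13. The list lay below the other genes (camera adjusted p = 0.0122), a call lost with an estimated correlation (adjusted p = 0.353). Of 21 activation markers, 9 were positive and 12 negative and 0 passed, with a median of -0.01 and a mean of 0.02, and the list was not called (camera adjusted p = 0.108). CTLA4, an inhibitory receptor, differed by -0.25, TNFRSF9 by 0.62, TNFRSF4 by 0.15 and CD38 by -0.08. Of 23 cytokines and chemokines, 15 were positive and 8 negative, with a median of 0.06, and 0 passed over all genes (camera adjusted p = 0.619). CCL5 differed by 0.86 (SE 0.11), the chemokine CCL4 by 0.64 (SE 0.16, and 0.18 for another probe) and IL21 by 0.41 (SE 0.19).

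Of 28 calcium and NFAT signalling genes, 0 passed, the median was -0.01 and the mean 0.04, and the list was not called (camera adjusted p = 0.108). ORAI3, a calcium channel of the plasma membrane, differed by 1.24 (SE 0.37, limma adjusted p = 0.283), NFAT5 by 0.30, STIM1, the calcium sensor of the endoplasmic reticulum, by -0.11 and ORAI1 by -0.11. Of 22 NF-kB targets, 0 passed and the median was -0.03 (camera adjusted p = 0.0160, and adjusted p = 0.324 with an estimated correlation). IRF1 differed by -0.20, TNIP2 by -0.19, TNIP1 by -0.16 and BCL2A1 by -0.13. Of 32 genes of the T cell receptor complex and its proximal signalling, 9 were positive and 23 negative, 0 passed and the median was -0.05 (camera adjusted p = 0.000160, and adjusted p = 0.324 with an estimated correlation). The receptor chain CD3E differed by -0.26, the kinase PRKCQ by -0.12 and the phosphatase PTPN6 by -0.15. Of 34 T lineage genes, 0 passed, and the median was 0.03 although camera's direction was below the other genes (adjusted p = 0.525). NOTCH1 differed by 0.19, FOXP3 by 0.73, TCF12 by 0.17 and MYB by 0.12. Probes of FOXP3 disagreed, from -0.60 to 0.73.

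Of 28 glycolysis and hypoxia genes, 3 were positive and 25 negative and 0 passed, with a median of -0.10. With 1 array left out the median ran from -0.06, without control replicate 3, to -0.24, without control replicate 1. PKM, a pyruvate kinase, differed by -0.34 (SE 0.15), the hexokinase HK1 by -0.23 (SE 0.12), the triose phosphate isomerase TPI1 by -0.20 (SE 0.11) and CA9, a carbonic anhydrase induced by hypoxia, by 0.54 (SE 0.21). The list lay below the other genes (camera adjusted p = 0.000142), a call lost with an estimated correlation (adjusted p = 0.353). It was the only one of the 12 lists still called among genes with a mean signal of at least -2, where 25 members had a median of -0.11 (camera adjusted p = 0.0119). Of 34 respiratory chain genes, 0 passed and the median was -0.04 (camera adjusted p = 0.000686, and adjusted p = 0.324 with an estimated correlation). CYC1 differed by -0.21, NDUFV1 by -0.14, UQCRC1 by -0.14 and NDUFS7 by -0.12, while another probe of NDUFS7 differed by 1.83.

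Of 26 genes of the unfolded protein and amino acid stress response, 0 passed and the median was -0.04 (camera adjusted p = 0.00208, and adjusted p = 0.324 with an estimated correlation). The amino acid transporter chain SLC3A2 differed by -0.24, SESN2 by -0.18, CEBPB by -0.12 and PHGDH by -0.10. Of 30 interferon response genes, 0 passed and the median was -0.04 (camera adjusted p = 0.00703, and adjusted p = 0.412 with an estimated correlation), with IFI44L at 0.33, IRF7 at -0.18, ISG20 at -0.16 and IFITM1 at -0.13. Of 18 heat shock genes, 0 passed, and the median was 0.05 although camera's direction was below the other genes (adjusted p = 0.525). Of 23 p53 targets, 0 passed, with a median of -0.01, a mean of 0.01 and a camera adjusted p of 0.139, and GADD45G differed by 0.29. Of 24 apoptosis regulators, 0 passed, and the median was near 0 although camera's direction was below the other genes (adjusted p = 0.118). CFLAR, an inhibitor of caspase 8 activation, differed by 0.45 (SE 0.16), XIAP by 0.16 and BID by -0.14. The 4 tested probes of CFLAR ran from -0.02 to 0.45, while another probe of XIAP was at 0.05 and another of BID near 0.

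Of 38 cell cycle genes, 17 were positive and 21 negative, 0 passed and the median was near 0 (camera adjusted p = 0.0200, and adjusted p = 0.639 with an estimated correlation). The replication helicase subunits MCM2 and MCM5 differed by -0.22 and -0.17, and CENPF, a kinetochore protein gene, by 0.20. Of 40 ribosomal protein genes, 0 passed and the median was near 0 (camera adjusted p = 0.00759, and adjusted p = 0.438 with an estimated correlation), with RPL18 at -0.17 and RPL15 at -0.14. Of 26 cholesterol synthesis genes, 0 passed and the median was -0.03 (camera adjusted p = 0.0200, and adjusted p = 0.574 with an estimated correlation), with CYP51A1 at 0.23, TM7SF2 at -0.21 and PMVK at -0.15. Of 25 sphingolipid genes, 0 passed and the median was near 0 (camera adjusted p = 0.0318, and adjusted p = 0.324 with an estimated correlation), with SMPD1 at -0.98, SGMS1, a sphingomyelin synthase, at 0.22 and CERS6, a ceramide synthase, at 0.18.

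Of 34 long non-coding RNAs listed by name, 15 were positive and 19 negative and 0 passed, with a median of -0.01 and a mean of 0.01. Camera placed the list below the other genes (adjusted p = 0.0318), a call lost with an estimated correlation (adjusted p = 0.353). KCNQ1OT1, an antisense RNA of an imprinted locus, differed by 0.59 (SE 0.23; 1.37 for another probe), C20orf204, which the list held as LINC00176, by 0.42 (SE 0.14), the nuclear RNA MALAT1 by 0.24 (SE 0.09) and RMRP, the RNA of RNase MRP, by -0.24 (SE 0.09). Of 18 reference genes, 0 passed and the median was near 0 (camera adjusted p = 0.0677), with PGK1 at -0.24. Of 28 markers of B cells, myeloid, erythroid and stromal cells, 20 were positive and 8 negative, 0 passed and the median was 0.07 (camera adjusted p = 0.559). The keratin genes KRT18, KRT8 and KRT19 differed by 0.97 (SE 0.27), 0.23 (SE 0.08) and 0.29 (SE 0.12), and CSF3R, the receptor of a granulocyte growth factor, by 0.39 (SE 0.10).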

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

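The restriction to a mean signal of at least -2 and the list test with each list at its estimated correlation were chosen after seeing the data. Of the counts of probes, genes and non-coding probes, 0 passed under every setting run except the following. Median scaling gave 4 probes, 4 genes and 1 non-coding probe, CLIP1-AS1. Without 1 array each, the counts ran from 0 to 1568 probes, 0 to 1211 genes and 0 to 607 non-coding probes, and the highest of each came without control replicate 3; the cause was not tested. With the title number as a replicate block the counts stayed at 0 probes, 0 genes and 0 non-coding probes, and 15 lists were called. The labels share 2 title numbers, and the deviations of the arrays with the same number correlated at 0.374 and 0.042 across probes, so the numbers were not taken to pair the samples. The place on the slide as a block gave 0 probes, with a smallest adjusted p of 0.0818. Of 564 values of 40 named probes under the alternatives, 17 passed, 16 of them without control replicate 3, and 33 had another sign, all of them for CD69, CNNM3-DT, EGR1, IL2RA, NFATC1 and TNF. Signal over background limits the dim probes, with 66.7% of probes well above it on control replicate 2.

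List calls by camera, given as adjusted p, moved more, and for most settings the cause was not tested. With normexp they were 0.0601 for the unfolded protein list, 0.118 for the immediate early and ribosomal lists, 0.120 for sphingolipid, 0.166 for NF-kB and cholesterol, 0.368 for long non-coding RNA and 0.561 for cell cycle. With quantile normalisation they were 0.0866 for glycolysis and hypoxia, 0.0911 for immediate early and T cell receptor, 0.158 for interferon, 0.377 for unfolded protein, 0.391 for respiratory chain, 0.497 for NF-kB, 0.575 for ribosomal, 0.630 for long non-coding RNA and sphingolipid, 0.665 for cholesterol and 0.911 for cell cycle. Without the detection filter they were 0.0550 for interferon, 0.0649 for ribosomal, 0.0727 for immediate early, 0.0825 for NF-kB, 0.0970 for cell cycle, cholesterol and long non-coding RNA, and 0.114 for sphingolipid. In the deposited value table they were 0.131 for T cell receptor, 0.171 for immediate early and interferon, 0.431 for unfolded protein, 0.508 for respiratory chain, 0.600 for NF-kB, 0.628 for ribosomal, 0.670 for cholesterol, long non-coding RNA and sphingolipid, and 0.899 for cell cycle. With the replicate block they were 0.145 for interferon, 0.0241 for calcium and heat shock, 0.0315 for p53 and 0.0373 for reference genes. With a mean signal of at least -2 they were 0.0555 for T cell receptor, 0.227 for immediate early and respiratory chain, 0.245 for unfolded protein, 0.356 for interferon, 0.687 for cholesterol, 0.758 for ribosomal and NF-kB, 0.797 for long non-coding RNA, 0.884 for cell cycle and 0.948 for sphingolipid. With an estimated correlation they were 0.324 for NF-kB, T cell receptor, unfolded protein, sphingolipid and respiratory chain, 0.353 for long non-coding RNA, glycolysis and hypoxia, and immediate early, 0.412 for interferon, 0.438 for ribosomal, 0.574 for cholesterol and 0.639 for cell cycle. That fit has 4 degrees of freedom. With each list at its estimated correlation and the degrees of freedom of the preset test they were 0.0552 for NF-kB, T cell receptor and sphingolipid, 0.0683 for unfolded protein, 0.0902 for respiratory chain, 0.228 for immediate early, 0.234 for glycolysis and hypoxia and for long non-coding RNA, 0.309 for interferon, 0.348 for ribosomal, 0.518 for cholesterol and 0.597 for cell cycle.

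With 1 array left out, 5 lists were called without control replicate 2, 7 without treated replicate 3, 11 without treated replicate 4, 12 without control replicate 3, 13 without treated replicate 2 and 15 without control replicate 1. The adjusted p ran from 0.000326 to 0.0805 for immediate early, 0.0357 to 0.358 for activation markers, 0.0187 to 0.756 for calcium, 0.0104 to 0.180 for NF-kB, 1.75e-05 to 0.795 for cell cycle, 0.0260 to 0.925 for p53 and 0.000252 to 0.0739 for interferon. It ran from 0.000345 to 0.0604 for unfolded protein, 1.75e-05 to 0.872 for cholesterol, 0.0114 to 0.207 for sphingolipid, 0.0178 to 0.197 for long non-coding RNA, 0.00197 to 0.0571 for ribosomal and 0.0232 to 0.379 for reference genes. Without treated replicate 3 the cell cycle list lay above the other genes (adjusted p = 0.747).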

Other observations

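The tests of the place on the slide, of the labelled contrast, of the spread of the activation genes and of the explanations for the gene lists were chosen after the results they bear on were seen. A later form of the test of correlation between genes, with unadjusted p and lists parted by their estimated correlation, was dropped, since the parting largely fixed its outcome. The first paragraphs below describe values chosen after they were seen.

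Several gene groups differed more between arrays of 1 label than between the labels. The mean of the 28 glycolysis and hypoxia genes, each centred on its own mean over the 6 arrays, was 0.13, -0.18 and -0.09 on treated replicates 2, 3 and 4 and -0.20, 0.14 and 0.19 on control replicates 1, 2 and 3 (log2). The 38 cell cycle genes were at 0.08, -0.14 and 0.05 and at -0.13, 0.07 and 0.07 in the same order, and the 26 cholesterol synthesis genes at 0.06, -0.15 and 0.06 and at -0.15, 0.09 and 0.09. The 25 immediate early genes were at -0.17, 0.22 and -0.08 and at 0.09, -0.04 and -0.02. The estimated correlation between genes of a list was 0.56 for cell cycle, 0.48 for cholesterol synthesis, 0.39 for glycolysis and 0.43 for the other cell type markers, against the preset 0.01. Over the 21 lists it ran from -0.04 for apoptosis regulators to 0.56, and over the 12 called lists from -0.01 for sphingolipid metabolism.

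Among genes well above background on all 6 arrays with a mean signal of at least -2, 61 had an unadjusted p under 0.05, labels that did not overlap and a difference of 2-fold or more, and all 61 were higher under the PMA and ionomycin label. None passed the limma adjusted threshold. The control arrays stood apart from each other in these genes, with a median SD of 0.66 against 0.09 for the treated label and a larger SD in 60 of 61. Their mean, each gene centred over the 6 arrays, was 0.62, 0.60 and 0.54 on treated replicates 2, 3 and 4 and -1.17, -0.67 and 0.09 on control replicates 1, 2 and 3. The 61 genes included LMO7DN (log2 difference 1.80, SE 0.42), the antisense RNA STARD4-AS1 (1.61, SE 0.43), LGI4 (1.53, SE 0.39) and TMCC2 (1.37, SE 0.32). They also included POU5F1, a pluripotency factor (1.20, SE 0.31, other probe 0.39), and the adaptor gene LAT2 (1.04, SE 0.32). Of the 21 with another tested probe, 9 had every other probe within 0.2 of no difference, among them PSMD10, a proteasome chaperone (1.22, other probes -0.10 to -0.05), PCNX4 (1.08, other probes -0.09 to 0.08) and LAT2 (other probe -0.09), while 5 had another probe at 2-fold or more.

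The activation genes had like levels under both labels. A spread too wide to exclude a 2-fold rise was argued against for 58 of the 69 genes (84.1%), whose intervals ended below it. It stays open for the exceptions, among them EGR1, EGR2, EGR3, NR4A3, TNFRSF9 and IL2. For an exchange of 1 array of each group, the largest absolute median over the 9 possible exchanges was 0.17, under the 0.5 set in advance. That value argues against an exchange only if the right grouping gives a median over 0.5. The points left open below mean this cannot be assumed, so an exchange is not excluded. The interval of the median is over genes, so it does not cover the spread between arrays or the choice of processing. Under the other settings the median of the 69 genes ran from -0.13 with median scaling to 0.08 with the replicate block. That the arrays do not hold the labelled contrast stays open, with an upper end of 0.048 for the interval of the median. CCL4 (0.64, interval 0.24 to 1.04), CCL5 (0.86) and IL2 near the floor go the other way, but another probe of CCL4 differed by 0.18. CCL5 and IL2 passed the threshold over all genes without control replicate 3 (limma adjusted p 0.0262 and 0.0196), a setting in which 1568 probes passed. Their mean signals of -5.14 and -6.94 lie among the dim probes, which were higher under the PMA and ionomycin label as a whole. Both differences were above the upper quartile of probes of like brightness. That quartile was 0.50 for probes from -6 to -5, where CCL5 lies, and 0.94 for probes below -6, where IL2 lies. The title code also differs between the labels, and a difference other than PMA and ionomycin was not tested. A response that is no longer visible at 24 h in this culture was not tested and stays open too.

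Dim probes were higher under the PMA and ionomycin label, with a median difference of 0.36 over the 7400 probes with a mean signal below -5. It was 0.03 with normexp, whose offset shrinks it by construction, and 0.05 under quantile normalisation, which makes the distributions alike. For the 1109 of these probes that were well above background on all 6 arrays it was 0.11. The detection filter also kept probes well above background under 1 label only, and the part that this filter plays was not tested. A higher background under the PMA and ionomycin label was tested on the negative control spots, which differed by -0.65 in log2 processed signal. That signal is already background-subtracted, so it cannot show whether the background differed before subtraction. Before subtraction, the mean signal of these spots was 39.41 under that label and 41.7 under the other. It was thus not higher on average, though the labels overlapped on single arrays. Background subtraction is a candidate explanation: in scaled intensity units the dim probes differed by 6.99 in processed signal, but by 0.64 in spot signal minus the signal beside the spot, with a spread of 2.47 over left-out arrays. The place on the slide cannot be told apart from the label, since as a block it gave 0.20 and rested on the single control array that shares a column with the treated arrays. Leaving out arrays moved the median from 0.18, without control replicate 2, to 0.47, without control replicate 3.

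Camera placed 12 of the fixed lists below the other genes. Dim genes in the background may account for part of this, since 1 of the 12, glycolysis and hypoxia, was still called among genes with a mean signal of at least -2. Correlation between genes may account for part of it as well, since 0 of the 12 stayed called with each list at its estimated correlation. That count overstates its effect, as T cell receptor (unadjusted p 0.00493), sphingolipid (0.00772), NF-kB (0.00788), unfolded protein (0.0130) and respiratory chain (0.0215) stayed under 0.05 before the adjustment over the 21 lists. A biological shift of the glycolysis genes was not tested and stays open.

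The 6 arrays make 10 splits into 3 and 3, too few for a share under 0.05. The real split had 0 probes, 0 genes and 0 non-coding probes past the threshold, and the highest of the other splits was 0 for each, so 10 of 10 splits gave as many. At an unadjusted p under 0.05 the real split had 5015 probes, the highest other 3742, and 1 split gave as many. The real split called 12 lists and the highest other 14, so 2 splits gave as many.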
